A study of Oncorhynchus mykiss with 24 samples.

How the data were processed

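RNA was measured in eggs and embryos of a trout hybrid at 4 stages, each cut across the animal-vegetal axis into section A (animal) and section B (vegetal). The labels give 24 libraries, 3 per stage and section. The count table holds 20 of them, and the other 4 (replicate 3 of both sections at 0 hpf and at 3 dpf) were not analysed here. Groups therefore held 2 libraries at 0 hpf and 3 dpf and 3 libraries at 1 hpf and 1 dpf. Per the labels, total RNA was depleted of ribosomal RNA and made into directional libraries, and fastp 0.23.4, STAR 2.7.11, HTSeq 2.0.4 and DESeq2 (no version, no stated role) were used. The strand setting of the counting and the genome builds are not stated.

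The deposited table of counts has 32765 genes, 22773 with an O. mykiss identifier (maternal species) and 9992 with an S. fontinalis identifier (paternal species). Its values are raw counts, and each gene has more than 30 counts in at least 1 library (lowest maximum 31). The authors also deposited 2 normalized tables, of unit signal, 1 per section. In each library the ratio of the counts to this signal was a single factor, so the signal holds no information beyond the counts, and the counts were used here. A deposited ortholog table and the identifiers themselves gave symbols: 8838 genes carried their own symbol, 8834 took one from the ortholog table, and 15093 had none. All 22773 O. mykiss identifiers were found in the reference table, 22254 of them as protein coding and 427 as long non-coding RNA. No coordinates are given, because the build behind the counts is not named. How reads that match both parental genomes, or several copies of a duplicated salmonid gene, were assigned is not stated either.

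Library totals ran from 5011274 to 9986001 counts, and the 20 most abundant genes took 1.56% to 4.33% of a library. Confidence intervals of a share are 95% exact binomial (Clopper-Pearson) intervals. Where a group had 0 counts, a fold was computed against a floor of 3 counts per library and written as a lower bound. Intervals and floors cover counting error only, since reads were not marked with molecular identifiers. Mean levels are edgeR's library-scaled counts (CPM) with trimmed mean of M values (TMM) factors, except in the comparison of the parental copies, which uses plain library totals.

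The main test was the quasi-likelihood test of edgeR 4.0.16 under R 4.3.3, on the counts of all 20 libraries in 1 model with a mean per stage and section, TMM factors and edgeR's expression filter. It tested 32502 genes (22724 O. mykiss, 9778 S. fontinalis) with Benjamini-Hochberg adjustment and a threshold of 0.05. The 13 contrasts were section A against B at each stage, consecutive stages within each section, and the change of the A against B difference between consecutive stages. The contrasts of 3 dpf with 0 hpf and 1 hpf served the next count. Genes higher at 3 dpf than at each of the 3 earlier stages, each time by a log2 fold change above 1, were counted with their mirror count. Genes with 0 counts in all 0 hpf and 1 hpf libraries of a section and at least 5 counts in each 3 dpf library were counted as detected after 1 hpf, without a condition on 1 dpf. Each group holds 2 or 3 eggs, and the spread behind a p-value was estimated from all 20 libraries, those of other stages included. A p-value therefore reflects the spread among these samples, and not only that of the eggs compared.

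Gene lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and again with an estimated correlation, over 21 lists and 13 contrasts, adjusted over 273 tests. The lists were vegetally localized RNAs of fish and frog eggs, germ plasm and primordial germ cell RNAs, oocyte and egg-specific maternal RNAs, early zygotic activation transcription factors and their early targets, Nodal and BMP signaling, Wnt and beta-catenin signaling, cell cycle and mitosis, histones, cytosolic ribosomal proteins, mitochondrially encoded genes, nuclear-encoded oxidative phosphorylation, maternal mRNA decay machinery, translational control, RNA polymerase II machinery, chromatin and DNA methylation regulators, motors and cytoskeleton, heat shock and stress, apoptosis and its regulators, and markers of sperm, ovarian follicle, blood, and liver and yolk. Some genes stand in more than 1 list. The mitochondrially encoded list had 0 genes in the table and was not tested. With the preset correlation 46 list tests passed, and with an estimated correlation 0 passed. Each camera p-value covers the list's genes of both species against all other tested genes, also where counts of O. mykiss members stand beside it. For 3 dpf, where S. fontinalis genes shift the background, camera was also run on the O. mykiss genes alone, chosen after seeing the data.

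Genes named in the text follow a rule. Per section or stage contrast it took, among genes with a symbol, an adjusted p under 0.05, a mean log CPM at or above the median (2.97) and no overlap between the libraries of the groups, the 8 with the largest increase and the 8 with the largest decrease, 1 locus per symbol. For changes of the section difference and for genes higher at 3 dpf than at each earlier stage it took 5 each way. It added up to 3 members per list with the smallest adjusted p, and always dazl, grip2, sybu, buc, wnt8a, gdf3, ddx4, dnd1, nanos3, zar1, pou5f3 and nanog where measured. Values of dnd1 and pou5f3 are not printed below. At 1 hpf, 1 dpf and 3 dpf the O. mykiss genes with the largest increase were named beside it, a choice made after seeing that S. fontinalis genes filled many places.

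The pairing of samples was checked with the deviation of each library from its group mean across O. mykiss genes, where genes are not independent replicates. Sections A and B of the same stage and number deviated together at 1 hpf, 1 dpf and 3 dpf (r from 0.388 to 0.736) but not at 0 hpf (r = −0.0105). Section A with section B of the other eggs of a stage reached r = 0.402 at 1 hpf and 0.274 at 1 dpf. For each egg of these stages its own r was higher. The egg as a block stands as an alternative for comparisons of the sections. Equal numbers at consecutive stages deviated in both directions (r from −0.458 to 0.440), and the replicate number as a block stands as an alternative too. Parental copies were compared over 3836 of 6027 one-to-one pairs of the ortholog table, those with both copies in the counts.

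On data simulated from these libraries, with 200 genes changed, the test recovered 27% of genes changed 2-fold and 85% of those changed 4-fold between the sections at 1 dpf, with 3 false calls among 31992 genes. For 3 dpf against 1 dpf it recovered 18% and 77% in section A with 5 false calls, and 22% and 82% in section B with 0. For the change of the section difference from 1 dpf to 3 dpf it recovered 4% and 49% with 0 false calls. The changed genes were drawn from those with a mean CPM above the median, so recovery of less abundant genes was not measured. Counts were drawn independently for each library around 1 mean per gene. Eggs shared by the sections, groups of eggs and the S. fontinalis rise at 3 dpf were not simulated, and the false calls do not cover them.

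The comparisons, the gene lists, the rule for named genes and these alternatives were fixed before the data were examined: DESeq2 1.42.0, RLE factors, library sizes alone, no filter or a minimum CPM of 1, the compared libraries alone, a replicate block, an absolute log2 fold change of at least 1, and leaving out each library in turn. TMM factors from the O. mykiss genes alone and a block for groups of eggs found in the counts were added after seeing the data.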

Results

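Eggs of O. mykiss (rainbow trout) were fertilized with sperm of S. fontinalis (brook trout), and RNA was sequenced by TOMO-seq, in which a frozen egg or embryo is cut along 1 axis and each section is sequenced separately. Section A was the animal part, where the cells form, and section B the vegetal part, which holds the yolk. The stages were 0 hours post fertilization (hpf), 1 hpf, 1 day post fertilization (dpf, about 32 to 64 cells) and 3 dpf (about 1000 cells). The labels of 0 hpf name both a non-fertilized and a freshly fertilized egg, and those of 1 hpf name both a 1-cell and an early cleavage stage. Each section was measured in 2 libraries at 0 hpf, 3 at 1 hpf, 3 at 1 dpf and 2 at 3 dpf. Library totals were 9180782 and 9346271 counts in section A at 0 hpf and 7634250 and 9986001 in section B. They ran from 8574091 to 9404008 (A) and from 8614708 to 9628963 (B) at 1 hpf, and from 6765611 to 7730696 (A) and from 5605030 to 8294788 (B) at 1 dpf. At 3 dpf they were 5923757 and 5011274 in section A and 6216107 and 6264179 in section B.

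Because only the father was S. fontinalis, counts on S. fontinalis genes address when the paternal genome is read. In section A at 3 dpf they made up 24.03% of replicate 1 (95% exact binomial interval 23.995% to 24.064%) and 22.45% of replicate 2 (22.414% to 22.487%), a mean of 23.2% ± 1.12 (SD, n = 2). In the other 18 libraries they made up 0.927% to 1.08% (mean 1.00% ± 0.0427, SD), including 1.00% ± 0.0279 (SD, n = 2) in section B at 3 dpf. The share in section A at 3 dpf was 22.6 times that in section A at 1 dpf. Between 9928 and 9935 S. fontinalis genes had counts in the 3 dpf section A libraries, against 4040 to 5681 in the others.

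**Figure D1:**
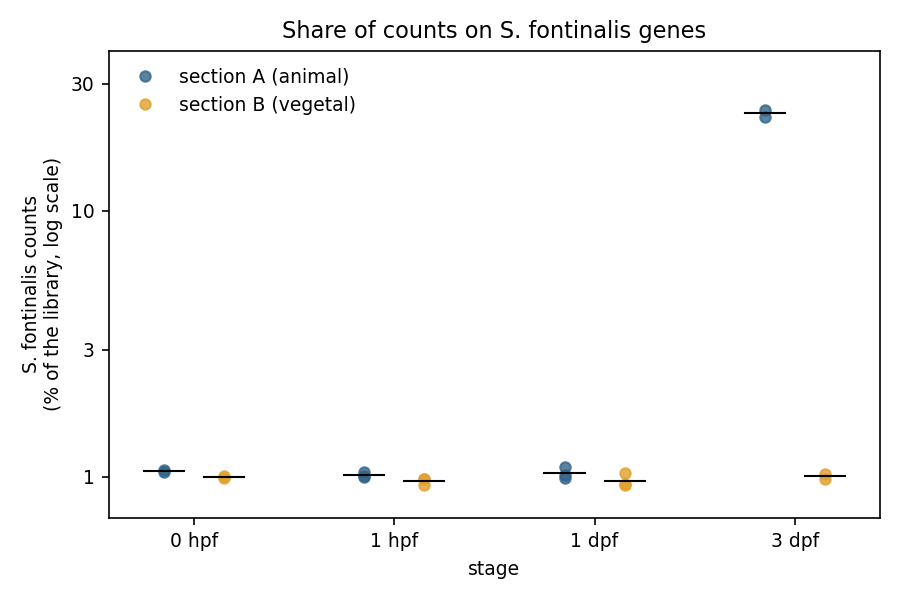
Percent of each library's counts on S. fontinalis genes (vertical, log scale) by stage (horizontal). Points are libraries of section A (blue) and section B (yellow), and black lines are group means. The 2 section A libraries at 3 dpf lie at 22.45% and 24.03%, and the other 18 lie between 0.927% and 1.08%.

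The comparison of section A with section B asked where RNA lies along the animal-vegetal axis. At 0 hpf, RNAs known to localize to the vegetal pole of fish and frog eggs were already lower in section A. grip2b (LOC110492486), a scaffold protein gene, measured 28.5 ± 9.58 CPM (mean ± SD, n = 2) in section A and 373 ± 15.3 in section B, a log2 fold change of −3.71 ± 0.53 (SE, adjusted p = 0.000352). trim36 (LOC110525254), a ubiquitin ligase gene, measured 69.1 ± 39.8 and 802 ± 62.6 CPM (log2 fold change −3.54 ± 0.48, adjusted p = 0.000205). sybu (LOC110518767), which links kinesin to cargo, dazl, a germ cell RNA-binding protein gene, and buc (LOC110489830), which organizes the Balbiani body, were lower by log2 fold changes of −2.70 ± 0.37, −2.48 ± 0.35 and −1.95 ± 0.30 (adjusted p = 0.000225, 0.000343 and 0.00058). Of the 30 measured O. mykiss members of the vegetal list, 0 were higher and 17 lower in section A (1 and 20 adjusted over the list alone). Camera gave an adjusted p = 2.19e-13 for that list, and an adjusted p = 0.275 with an estimated correlation.

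Other genes lower in section A at 0 hpf were kpna3, a nuclear import receptor gene (14.0 ± 10.7 against 181 ± 7.57 CPM, n = 2 each, log2 fold change −3.69 ± 0.49), pip4p2 (−3.91 ± 0.53) and si:ch211-203d1.3 (−4.22 ± 0.63), with adjusted p = 0.00017, 0.000198 and 0.000488. The Wnt pathway genes axin1 (LOC110485340) and tnksa, and srcap, a chromatin remodeler gene, were lower by −2.50 ± 0.32, −2.22 ± 0.26 and −2.58 ± 0.27 (adjusted p = 0.000134, 8.53e-05 and 7.01e-05). The cytoskeleton genes ndel1a and tpm3 were lower by −1.79 ± 0.22 and −1.99 ± 0.27 (adjusted p = 0.0001 and 0.000233). Higher in section A were exd2, an exonuclease gene (603.5 ± 26.2 against 117 ± 95.3 CPM, log2 fold change 2.36 ± 0.40, adjusted p = 0.00148), txlng (2.19 ± 0.34, adjusted p = 0.000726), cnot4a (LOC110524813) of the mRNA decay list (2.05 ± 0.34, adjusted p = 0.00113) and orc1 of the replication origin complex (1.60 ± 0.26, adjusted p = 0.00108). edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1269 genes, 329 O. mykiss genes higher and 901 lower in section A, and 7 and 32 S. fontinalis genes. Without section A replicate 1 the count was 260. With the egg as a block it was 3037, with 1279 O. mykiss genes higher and 1626 lower, and DESeq2 called 2520, with 1062 and 1356, so the excess of lower genes was smaller there.

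At 1 hpf the same direction held for these genes with more libraries. hwa, a membrane protein gene that sets the dorsal side in zebrafish, measured 2.54 ± 0.451 CPM in section A and 64.0 ± 21.1 in section B (n = 3 each, log2 fold change −4.64 ± 0.53, adjusted p = 6.43e-06). grip2b reached −4.73 ± 0.46, trim36 (LOC110525254) −4.61 ± 0.41, sybu (LOC110518767) −3.73 ± 0.32, dazl −3.29 ± 0.30 and rtn3 −2.22 ± 0.19 (adjusted p = 8.57e-07, 4.05e-07, 2.59e-07, 4.56e-07 and 2.37e-07). Among the 30 O. mykiss vegetal list members 2 were higher and 20 lower (2 and 20 adjusted over the list alone; camera adjusted p = 2.39e-10, adjusted p = 0.275 with an estimated correlation). Outside that list, cracr2b (2.22 ± 0.181 against 126 ± 53.6 CPM, −5.81 ± 0.63) and gipc2 (5.38 ± 1.34 against 138 ± 23.4, −4.68 ± 0.48) were lower (adjusted p = 3.46e-06 and 1.78e-06). Of 23 germ plasm and primordial germ cell genes 2 were higher and 6 lower (2 and 8 adjusted over the list alone; camera adjusted p = 0.0658). hook2 and ddx4 were lower by −2.38 ± 0.27 and −1.09 ± 0.21 (adjusted p = 5.99e-06 and 0.00111), and buc (LOC110489830) of the vegetal list by −2.08 ± 0.25 (adjusted p = 7.93e-06).

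Among the genes with the largest increase in section A at 1 hpf, the ubiquitin ligase genes ubr4 and huwe1 measured 323 ± 31.3 and 217.5 ± 18.2 CPM in section A against 19.1 ± 9.10 and 19.1 ± 9.91 in section B (log2 fold changes 4.08 ± 0.65 and 3.50 ± 0.58, adjusted p = 0.000184 and 0.000268). stk40, a kinase-like gene (295 ± 35.0 against 27.5 ± 12.2 CPM), and ckap5, a microtubule polymerase gene (197 ± 25.8 against 21.5 ± 9.38 CPM), were higher by 3.42 ± 0.37 and 3.19 ± 0.42 (adjusted p = 3.8e-06 and 2.57e-05). Of 126 O. mykiss ribosomal protein genes 50 were higher and 0 lower in section A (61 and 0 adjusted over the list alone), among them rpl10 (56.3 ± 3.26 against 15.9 ± 3.38 CPM, 1.82 ± 0.27), with camera adjusted p = 2.39e-10 and an adjusted p = 0.376 with an estimated correlation. Of 74 oxidative phosphorylation genes 33 were higher and 1 lower (37 and 1 adjusted over the list alone; camera adjusted p = 2.85e-09, adjusted p = 0.371 with an estimated correlation). atp5f1d and atp5f1c were among the higher ones (2.02 ± 0.31 and 1.84 ± 0.28), and sdhc was the lower one (−2.37 ± 0.34). Of 91 chromatin regulators 43 were higher and 5 lower (49 and 7 adjusted over the list alone; camera adjusted p = 1.26e-06, adjusted p = 0.371 with an estimated correlation), with kmt2bb higher (352 ± 39.0 against 53.2 ± 16.8 CPM, 2.73 ± 0.35) and srcap lower (−3.41 ± 0.23). RNA polymerase II machinery was higher in 19 and lower in 1 of 57 genes (20 and 4 adjusted over the list alone; camera adjusted p = 0.0131, adjusted p = 0.371 with an estimated correlation).

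Of 70 cell cycle genes 23 were higher and 12 lower in section A at 1 hpf (24 and 15 adjusted over the list alone; camera adjusted p = 0.174). The replication genes orc1 (378 ± 41.6 against 93.5 ± 13.1 CPM, n = 3 each), mcm4 (148 ± 4.30 against 34.1 ± 4.51) and mcm7 (254 ± 16.2 against 94.2 ± 9.53) were higher by 2.02 ± 0.22, 2.12 ± 0.27 and 1.43 ± 0.18 (adjusted p = 3.23e-06, 1.99e-05 and 1.75e-05). In the Wnt list 6 of 41 O. mykiss genes were higher and 13 lower (7 and 14 adjusted over the list alone; camera adjusted p = 0.118), with axin1 (LOC110485340) at 11.4 ± 1.56 against 159.5 ± 46.0 CPM and tnksa at −2.90 ± 0.22. The test called 5926 genes at 1 hpf, 2848 O. mykiss genes higher and 2679 lower in section A, and 206 and 193 S. fontinalis genes. The S. fontinalis ubr4 gene had 5.11 ± 1.67 CPM in section A and 0.152 ± 0.0806 in section B, the side on which the O. mykiss copy lay.

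At 1 dpf, with 32 to 64 cells on the animal side, the sections differed in much the same way. Across 15423 O. mykiss genes the log2 fold changes at 1 hpf and 1 dpf correlated at r = 0.948, and 4761 of the 4761 genes called at both stages had the same direction (across genes, which are not independent replicates). grip2b (56.1 ± 37.5 against 853 ± 236 CPM, n = 3 each, −3.93 ± 0.44), sybu (LOC110518767, 114 ± 2.64 against 1161 ± 132, −3.35 ± 0.31), kpna3 (26.1 ± 12.0 against 428 ± 96.8, −4.04 ± 0.40) and dazl (24.8 ± 6.16 against 174 ± 47.2, −2.81 ± 0.29) were lower in section A (adjusted p = 4.41e-06, 6.59e-07, 1.35e-06 and 1.85e-06). cracr2b, sema5bb, abhd17aa and pip4p2 were lower by −4.78 ± 0.58, −4.67 ± 0.59, −4.03 ± 0.41 and −3.94 ± 0.42. The vegetal list again had 2 members higher and 20 lower of 30 (2 and 20 adjusted over the list alone; camera adjusted p = 1.92e-09, adjusted p = 0.275 with an estimated correlation). gdf3, a Nodal-related growth factor gene, was lower by −1.12 ± 0.18 (adjusted p = 0.000193). Of 9 histone genes 0 were higher and 5 lower (0 and 5 adjusted over the list alone; camera adjusted p = 0.00608, adjusted p = 0.614 with an estimated correlation).

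On the animal side at 1 dpf were stk40 (258 ± 14.0 against 17.9 ± 9.34 CPM, n = 3 each, 3.84 ± 0.39), ubr4 (302 ± 27.9 against 20.4 ± 16.1, 3.88 ± 0.65), huwe1 (log2 fold change 3.78 ± 0.59) and aox6 (40.3 ± 12.6 against 3.31 ± 2.20, 3.57 ± 0.40), with adjusted p = 1.51e-06, 0.000248, 0.000136 and 4.55e-06. actb1, a cytoplasmic actin gene, stood at 16.5 ± 12.6 against 1.40 ± 0.598 CPM (3.55 ± 0.81, adjusted p = 0.00346). Ribosomal protein genes were higher in 59 and lower in 0 of 126 (67 and 0 adjusted over the list alone; camera adjusted p = 1.67e-10, adjusted p = 0.371 with an estimated correlation), and oxidative phosphorylation genes higher in 35 and lower in 2 of 74 (44 and 2 adjusted over the list alone; camera adjusted p = 1.92e-09, adjusted p = 0.371 with an estimated correlation). Chromatin regulators were higher in 45 and lower in 11 of 91 (48 and 13 adjusted over the list alone; camera adjusted p = 5.13e-05, adjusted p = 0.376 with an estimated correlation), with bptf (1.75 ± 0.20) and supt16h of the polymerase II list (1.23 ± 0.16) among the higher genes. edgeR called 6947 genes at 1 dpf, 3250 O. mykiss genes higher and 3141 lower in section A, and 313 and 243 S. fontinalis genes. With library sizes in place of TMM factors the directions were 4402 higher and 2688 lower, against 3563 and 3384 over both species.

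**Figure D2:**
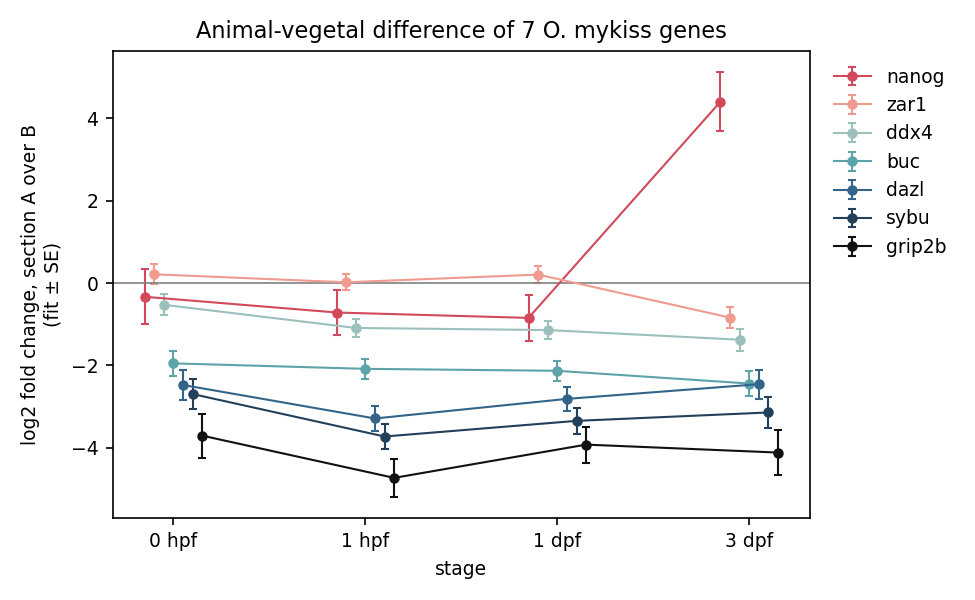
Log2 fold change of section A over section B (vertical, fitted value ± SE) by stage (horizontal) for 7 O. mykiss genes named in advance; nanog is locus LOC110535236, buc LOC110489830, sybu LOC110518767 and grip2b LOC110492486. Each section holds 2 libraries at 0 hpf and 3 dpf and 3 libraries at 1 hpf and 1 dpf. grip2b, sybu, dazl and buc lie below 0 at each stage, and this nanog locus reaches 4.41 at 3 dpf. The other O. mykiss nanog locus is not drawn.

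At 3 dpf the animal section held many RNAs that were not detected in the vegetal section. O. mykiss her5, a hairy-related repressor gene, reached 96.4 ± 30.2 CPM in section A (n = 2), HMGA1, an architectural chromatin protein gene, 96.5 ± 4.75, and the ventral homeobox genes vent and vox 88.9 ± 22.0 and 40.7 ± 7.70, each with 0 counts in section B (n = 2). Against a floor of 3 counts per library these were at least 184-fold, 184-fold, 170-fold and 77.8-fold higher. S. fontinalis eef1a1b, a translation elongation factor gene, reached 676 ± 258 CPM, phlpp2 639 ± 61.1, the arginine methyltransferase gene prmt1 439 ± 175 and eef2b 295 ± 10.7, at least 1293-fold, 1221-fold, 839.9-fold and 564-fold higher on the same floor. O. mykiss nanog (LOC110535236), an activator of the zygotic genome in zebrafish, measured 666 ± 511 CPM in section A and 31.4 ± 19.96 in section B (4.41 ± 0.72, adjusted p = 9.57e-05). Of 58 O. mykiss early zygotic genes 36 were higher and 8 lower in section A (37 and 8 adjusted over the list alone), and 14 of 14 S. fontinalis members were higher. Camera gave an adjusted p = 0.000158 for this list and an adjusted p = 0.275 with an estimated correlation.

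Of 126 O. mykiss ribosomal protein genes 120 were higher in section A at 3 dpf and 0 lower (121 and 0 adjusted over the list alone), and 55 of 55 S. fontinalis ones were higher (camera adjusted p = 1.51e-15, adjusted p = 0.371 with an estimated correlation). Translational control genes went both ways, 33 higher and 19 lower of 73 (34 and 19 adjusted over the list alone; camera adjusted p = 0.0603), and this list passed with the egg as a block. rps7 measured 62.5 ± 10.4 against 3.07 ± 0.810 CPM (n = 2 each, 4.34 ± 0.35), rplp0 408 ± 112 against 49.9 ± 12.6 (3.03 ± 0.25) and rpsa 136 ± 6.76 against 12.6 ± 3.63 (3.44 ± 0.24), with adjusted p = 2.24e-07, 2.8e-07 and 5.55e-08. The replication licensing gene cdt1 (LOC110506411, 168.5 ± 67.6 against 1.18 ± 1.16 CPM, 7.11 ± 0.82) and ago2 (LOC110488009, 180 ± 48.1 against 5.21 ± 3.24, 5.10 ± 0.41) were higher (adjusted p = 3.57e-06 and 2.06e-07), and the maternal cyclin genes ccna1 and ccnb2 were lower by −1.89 ± 0.19 and −1.65 ± 0.18. brd2a, smarca5 and tp53inp1 were higher by 1.73 ± 0.19, 1.52 ± 0.19 and 3.72 ± 0.50 (adjusted p = 2.5e-06, 7.73e-06 and 1.37e-05).

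Vegetal RNAs stayed on the vegetal side at 3 dpf. hwa (3.53 ± 2.62 against 82.8 ± 15.1 CPM, n = 2 each, −4.52 ± 0.66), grip2b (61.1 ± 42.8 against 1064 ± 239, −4.12 ± 0.54), trim36 (LOC110525254, 116 ± 59.8 against 2068 ± 475, −4.16 ± 0.49) and mroh1 (30.3 ± 9.92 against 661 ± 69.2, −4.44 ± 0.44) were lower in section A (adjusted p = 3.5e-05, 1.22e-05, 4.72e-06 and 1.04e-06). sybu (LOC110518767), dazl, buc (LOC110489830) and ddx4 were lower by −3.14 ± 0.38, −2.46 ± 0.35, −2.44 ± 0.31 and −1.38 ± 0.26. The translational regulator genes cpeb4b (LOC110537780) and cpeb4a were lower by −2.30 ± 0.19 and −1.90 ± 0.17. In the vegetal list 2 of 30 O. mykiss genes were higher and 23 lower (2 and 23 adjusted over the list alone; camera adjusted p = 0.000164, adjusted p = 0.376 with an estimated correlation), while 5 of its 8 S. fontinalis genes were higher and 1 lower. Germ plasm genes were higher in 4 and lower in 11 of 23 (4 and 11 adjusted over the list alone; camera adjusted p = 0.205). edgeR called 18133 genes at 3 dpf, 3461 O. mykiss genes higher and 6161 lower in section A, and 8437 and 74 S. fontinalis genes. The S. fontinalis counts lowered the median O. mykiss log2 fold change to −0.33. With factors from the O. mykiss genes alone 4733 were higher and 4176 lower, and RLE factors gave 4552 and 4412.

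The comparison of consecutive stages asked which RNAs change before and after the embryo starts its own transcription. Between 0 hpf and 1 hpf gapdh, the glycolytic enzyme gene, was the single gene called. In section B it measured 17.1 ± 0.706 CPM at 1 hpf (n = 3) and 64.5 ± 24.1 at 0 hpf (n = 2), a log2 fold change of −1.92 ± 0.26 (edgeR quasi-likelihood, adjusted p = 0.0297). It was not called without 1 hpf section B replicate 1 (adjusted p = 0.0539), without 0 hpf section B replicate 2 (−1.47, adjusted p = 0.593), without 1 hpf section B replicate 2 (adjusted p = 0.229) or replicate 3 (adjusted p = 0.145), or with groups of eggs found in the counts as a block (−1.41, adjusted p = 0.192). In section A edgeR called 0 genes between 0 hpf and 1 hpf, with 3170 at an unadjusted p under 0.05, while DESeq2 called 369. In section B 4890 genes had an unadjusted p under 0.05 and DESeq2 called 1423, and without 1 hpf section B replicate 1 edgeR called 42. As lists in section B, vegetal, germ plasm and Wnt genes moved up (camera adjusted p = 0.00201, 0.00676 and 0.0279) and ribosomal protein and oxidative phosphorylation genes down (both 5.33e-07), with 0 single genes called and adjusted p = 0.457, 0.275, 0.295, 0.457 and 0.371 with an estimated correlation.

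Between 1 hpf and 1 dpf, the first cell cycles, grip2b measured 26.2 ± 5.55 and 56.1 ± 37.5 CPM in section A and 697 ± 170 and 853 ± 236 in section B (n = 3 each), and dazl 144 ± 29.9 and 174 ± 47.2 in section B. edgeR called 0 genes in section A and 0 in section B, with 2317 and 2756 at an unadjusted p under 0.05, and DESeq2 called 99 and 105. Without 1 hpf replicate 1 edgeR called 22 genes in section A and 192 in section B. In section A camera moved the vegetal list up (adjusted p = 0.0244) and histones down (adjusted p = 0.0163), with adjusted p = 0.661 and 0.714 with an estimated correlation. wnt8a (LOC110489479), a Wnt ligand gene, had 0 counts in each 0 hpf library and 17.1 ± 22.2 CPM (n = 3) in section B at 1 hpf, and was not called in any contrast.

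Between 1 dpf and 3 dpf, S. fontinalis genes rose together in section A. The S. fontinalis copies of prmt1 (439 ± 175 CPM, n = 2), nanog (244 ± 125), the nucleolar protein genes nop56 and nop58 (196 ± 95.2 and 149 ± 60.4), pprc1 (178 ± 3.93) and myom1a (201 ± 44.2) had 0 counts in each 1 dpf section A library (n = 3). They were at least 1136-fold, 631-fold, 506.8-fold, 385.6-fold, 459.5-fold and 518.7-fold higher at 3 dpf on the floor of 3 counts per library. The S. fontinalis gene LOC129862859, which the ortholog table names fshr, a name that was not checked, stood at 319 ± 51.3 CPM, with 0 to 1 counts in each of the other 18 libraries. Of 9778 S. fontinalis genes tested 8688 rose and 24 fell. The table keeps genes with over 30 counts in some library, which favours genes present in these libraries, and with a CPM of at least 1 in at least 3 libraries 3543 of 4681 rose and 15 fell.

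O. mykiss genes rose with them, among them vent, her5 and nanog of the early zygotic list. akap12b, slc22a5, slc7a7 and apoeb stand outside that list and are named for their large increase. vent (88.9 ± 22.0 CPM, n = 2), akap12b (93.3 ± 18.3) and the carnitine transporter gene slc22a5 (108 ± 45.4) had 0 counts in each 1 dpf section A library (n = 3) and were at least 229.9-fold, 241-fold and 279.5-fold higher. her5 rose from 0.0408 ± 0.0706 to 96.4 ± 30.2 CPM, slc7a7 from 0.0820 ± 0.0710 to 169 ± 69.4 and the apolipoprotein gene apoeb from 0.0815 to 81.3 ± 4.66. nanog (LOC110535236) rose from 12.6 ± 7.34 to 666 ± 511 CPM (5.72 ± 0.65, adjusted p = 2.6e-06), while the other O. mykiss nanog locus measured 234 ± 73.6 and 254 ± 103 CPM (adjusted p = 0.742). nanos3 (LOC110495042), a germ cell gene, rose from 0.862 ± 0.126 to 20.1 ± 1.32 CPM (4.52 ± 0.95, adjusted p = 0.000735), and smad4, the common Nodal and BMP effector gene, from 2.41 ± 1.75 to 44.6 ± 8.73 (4.19 ± 0.82, adjusted p = 0.00041). Of 58 O. mykiss early zygotic genes 37 rose and 8 fell (37 and 8 adjusted over the list alone), and 14 of 14 S. fontinalis members rose. Camera gave an adjusted p = 3.56e-05 and an adjusted p = 0.275 with an estimated correlation. On the O. mykiss genes alone the adjusted p = 3.22e-18, and adjusted p = 0.0259 with an estimated correlation.

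Ribosomal protein genes rose as well in section A from 1 dpf to 3 dpf. Of 126 O. mykiss ribosomal protein genes 103 rose and 0 fell (107 and 0 adjusted over the list alone), and 55 of 55 S. fontinalis ones rose (camera adjusted p = 1.28e-10, adjusted p = 0.371 with an estimated correlation). rplp0 rose from 67.7 ± 14.7 (n = 3) to 408 ± 112 CPM (n = 2), rps2 from 84.2 ± 13.02 to 417 ± 21.2 and rpl17 from 3.18 ± 0.354 to 46.1 ± 5.49, log2 fold changes of 2.59 ± 0.22, 2.31 ± 0.21 and 3.85 ± 0.35 (adjusted p = 1.09e-07, 2.45e-07 and 3.4e-07). cdt1 (LOC110506411) rose from 1.89 ± 1.09 to 168.5 ± 67.6 CPM (6.48 ± 0.65), ago2 (LOC110488009) from 13.5 ± 1.17 to 180 ± 48.1 (3.74 ± 0.32) and igf2bp3, an mRNA-binding protein gene, from 21.5 ± 2.12 to 94.8 ± 22.7 (2.14 ± 0.19), with adjusted p = 7.65e-07, 1.57e-07 and 2.3e-07. The chromatin genes smarca5, srcap and cbx5 rose by 1.58 ± 0.17, 1.75 ± 0.23 and 1.49 ± 0.21, and the stress response genes tp53inp1 and ccng1 by 3.60 ± 0.42 and 1.20 ± 0.18 (adjusted p = 1.34e-06, 1.27e-05, 1.87e-05, 3.38e-06 and 3.24e-05).

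RNAs specific to the oocyte and egg fell in section A over the same interval: 0 of 25 O. mykiss genes rose and 17 fell (0 and 18 adjusted over the list alone), and 12 fell with factors from the O. mykiss genes alone. Camera over the list's genes of both species gave an adjusted p = 0.00199 and an adjusted p = 0.275 with an estimated correlation. The S. fontinalis rise shifts the background of this test, so its p-value does not rest on the O. mykiss fall alone. zar1, needed for the egg-to-embryo transition, fell from 54.6 ± 10.5 (n = 3) to 21.3 ± 9.08 CPM (n = 2), mos, the meiotic arrest kinase gene, from 92.0 ± 21.9 to 37.7 ± 0.0565, and figla, an oocyte transcription factor gene, from 42.3 ± 5.45 to 15.3 ± 2.71, log2 fold changes of −1.36 ± 0.24, −1.29 ± 0.21 and −1.47 ± 0.28 (adjusted p = 0.000173, 9.26e-05 and 0.000345). The piRNA pathway genes tdrd7a and piwil1 fell by −1.29 ± 0.20 and −1.01 ± 0.16, and the translational regulators cpeb4b (LOC110533338) and cpeb4a by −1.75 ± 0.18 and −1.47 ± 0.15. The mitotic genes cdc25b and kif11 fell by −1.62 ± 0.17 and −1.39 ± 0.15 (adjusted p = 1.2e-06 and 1.26e-06). The largest named decreases were micos10 (17.9 ± 2.85 to 2.49 ± 1.74 CPM, −2.82 ± 0.44), spen (175 ± 31.9 to 32.3 ± 1.80, −2.44 ± 0.40), tshz2 (75.9 ± 4.98 to 14.9 ± 0.312, −2.35 ± 0.23), limk1a (LOC110503880, 24.7 ± 3.65 to 4.91 ± 0.412, −2.32 ± 0.61), klf6a (63.2 ± 11.6 to 13.3 ± 0.944, −2.25 ± 0.41) and senp6a (−2.23 ± 0.22), with adjusted p = 5.52e-05, 8.71e-05, 5.33e-07, 0.00375, 0.000224 and 8.27e-07.

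Other lists changed in both directions among the O. mykiss genes of section A. Cell cycle genes rose in 9 and fell in 23 of 70 (9 and 22 adjusted over the list alone), which turned to 15 and 13 with factors from the O. mykiss genes alone, and motors and cytoskeleton rose in 6 and fell in 21 of 78 (3 and 17), which turned to 13 and 11. Translational control rose in 30 and fell in 19 of 73 (31 and 19 adjusted over the list alone; camera adjusted p = 0.0535), and chromatin regulators in 30 and 16 of 91 (30 and 16; camera adjusted p = 0.00328, adjusted p = 0.491 with an estimated correlation). With library sizes alone the latter were 21 and 20. Both camera p-values include the S. fontinalis members of these lists, 44 and 83 genes in the table. Oxidative phosphorylation rose in 1 and fell in 12 of 74 genes (0 and 10 adjusted over the list alone), or 4 and 8 with the O. mykiss factors. edgeR's test called 16630 genes. The O. mykiss genes were 2656 higher and 5262 lower around a median log2 fold change of −0.33, which became 3889 and 2774 with factors from the O. mykiss genes alone, 3733 and 2978 with RLE factors and 3848 and 3399 with DESeq2. A decrease close to that median is therefore a matter of scaling, while the decreases named above were called under each of these.

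**Figure D3:**
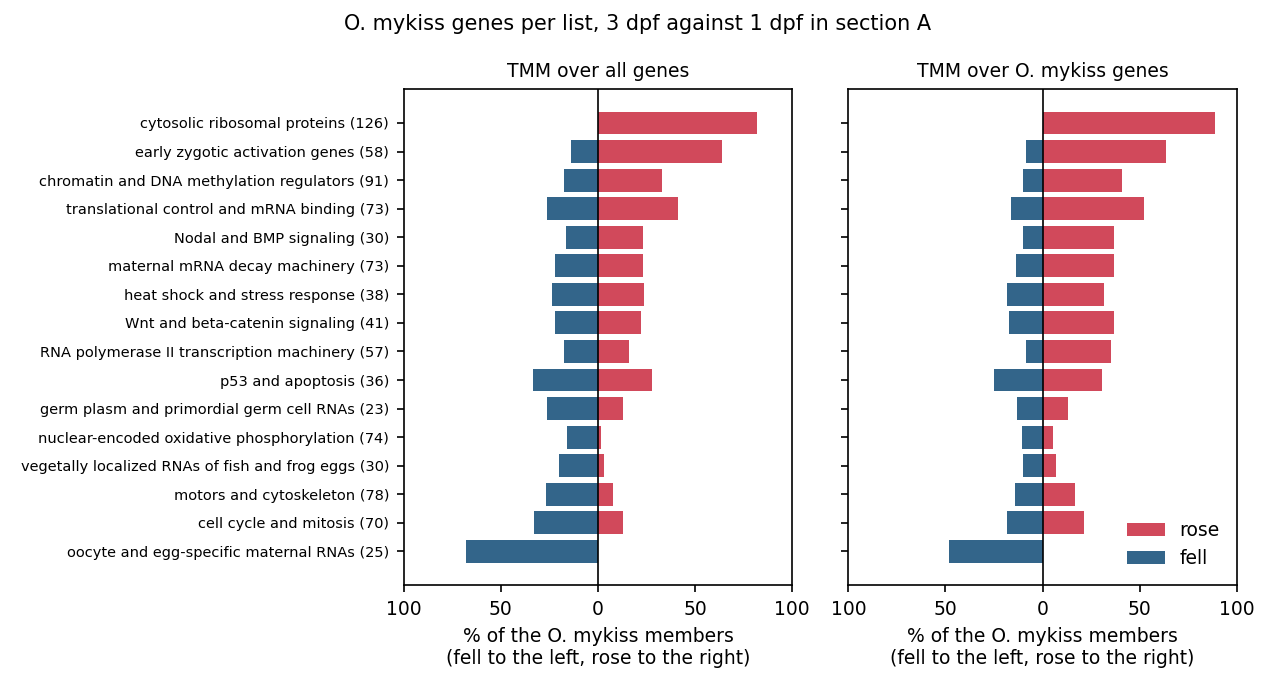
Percent of O. mykiss genes per list that rose (red, right) or fell (blue, left) between 1 dpf and 3 dpf in section A. Brackets give the number of tested genes. Factors are from all genes (left panel) and from the O. mykiss genes alone (right panel). The lists of histones and of sperm, follicle, blood, and liver and yolk markers hold few genes and are not drawn. Ribosomal protein genes rose in 103 of 126 and oocyte and egg genes fell in 17 of 25 in the left panel; cell cycle genes go from 9 up and 23 down to 15 and 13.

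In section B few RNAs differed detectably between 1 dpf and 3 dpf. grip2b measured 853 ± 236 CPM at 1 dpf (n = 3) and 1064 ± 239 at 3 dpf (n = 2), dazl 174 ± 47.2 and 156 ± 58.0, ddx4 305 ± 49.8 and 304 ± 104, zar1 47.4 ± 5.01 and 38.0 ± 1.40, and nanog (LOC110535236) 22.7 ± 12.2 and 31.4 ± 19.96. edgeR called 0 genes, with 1903 at an unadjusted p under 0.05, and DESeq2 called 78. Without 3 dpf section B replicate 1 edgeR called 2. Against 0 hpf, edgeR called 58 O. mykiss genes in section B at 3 dpf, 28 higher and 30 lower, or 21 and 62 with library sizes, while DESeq2 called 1167 genes, 756 higher and 411 lower. Blocks for the replicate number and for groups of eggs gave 411 and 625. As lists, chromatin regulators and motors moved up (camera adjusted p = 0.048 and 0.021) and ribosomal protein and oxidative phosphorylation genes down (0.0135 and 0.034) from 1 dpf to 3 dpf, none of which passed with an estimated correlation.

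The change of the section difference between stages addresses relative RNA levels along the axis. It cannot tell movement between the sections from gain or loss of RNA within 1 of them. A change towards a section means a higher level there relative to the other section. For 1 dpf to 3 dpf the stage contrasts called 16630 genes in section A and 0 in section B. From 0 hpf to 1 hpf and from 1 hpf to 1 dpf edgeR called 0 genes, with 692 and 644 at an unadjusted p under 0.05, and DESeq2 called 1 and 0. As lists, ribosomal protein and oxidative phosphorylation genes shifted towards section A from 0 hpf to 1 hpf (camera adjusted p = 3.26e-12 and 4.53e-07, both with adjusted p = 0.371 with an estimated correlation), and vegetal, Wnt and germ plasm genes towards section B (0.0135, 0.0178 and 0.0225), which did not pass with an estimated correlation. These shifts rest on 2 eggs at 0 hpf, of which replicate 2 had a weaker section difference in general (slope of its A over B log2 ratios on the mean of the other eggs 0.454, against 0.866 to 1.21 in the 8 later eggs), which would move such lists alike. From 1 dpf to 3 dpf 6616 genes changed, 1072 O. mykiss genes towards section A and 2470 towards section B, and 3069 and 5 S. fontinalis genes. Of 126 O. mykiss ribosomal protein genes 63 shifted towards section A and 0 towards section B (87 and 0 adjusted over the list alone; camera adjusted p = 1.05e-10, adjusted p = 0.371 with an estimated correlation), and early zygotic genes shifted in 11 and 2 of 58 (14 and 2; adjusted p = 6.29e-06, adjusted p = 0.275 with an estimated correlation). runx3 shifted towards section B (log2 −2.47 ± 0.24, adjusted p = 1.26e-05), at 15.0 ± 2.27 CPM in section A and 75.3 ± 6.38 in section B at 3 dpf (n = 2 each). Without 3 dpf section A replicate 1 the count was 4010, and with factors from the O. mykiss genes alone the O. mykiss directions turned to 1623 towards section A and 1052 towards section B.

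Candidates for new transcription, the stated focus of the study, were genes higher at 3 dpf than at each earlier stage. In section A they numbered 9737 (1444 O. mykiss, 8293 S. fontinalis), against 1504 in the mirror direction (1496 O. mykiss). The mirror count was 505 with factors from the O. mykiss genes alone and 2434 with library sizes. A CPM of at least 1 in at least 3 libraries gave 4249 candidates (1172 O. mykiss, 3077 S. fontinalis) and a mirror count of 1135. That minimum drops genes found only in the 2 section A libraries of 3 dpf. By the named rule the 9737 candidates included S. fontinalis prmt1, fshr, nanog, myom1a and nop56 and O. mykiss si:ch211-107n13.1 (134 ± 17.8 CPM, n = 2), slc22a5, akap12b, vent and slc7a7. In section B edgeR called 0 genes in either direction, and DESeq2 called 0 higher and 3 lower. Genes with 0 counts at 0 hpf and 1 hpf and at least 5 in each 3 dpf library, whatever their counts at 1 dpf, numbered 2429 in section A (81 O. mykiss, 2348 S. fontinalis), with a mirror count of 0, and 0 in section B with a mirror count of 2. In section B, leaving out 3 dpf replicate 1 or replicate 2 gave 7 and 13. The O. mykiss genes with most counts among the 81 were fetub (647 and 274 counts in the 2 libraries), LOC118947133 (393 and 335) and snai1b (309 and 337). Next came the claudin gene cldne (312 and 174), eps8l1b (331 and 147), aplnrb (210 and 158) and the notochord homeobox gene noto (131 and 149). Picked by name further down, with others passed over, were id1 (97 and 96), dusp6 (50 and 98), chrd, a BMP antagonist (53 and 74), and bbc3, an apoptosis gene (60 and 68).

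Parental copies of the same gene were then compared in section A at 3 dpf. Of 3836 one-to-one pairs, 73 had both copies under 1 CPM in each library before 3 dpf and at least 10 CPM together at 3 dpf. Their median S. fontinalis share was 51.5% (quartiles 41.8% and 66.1%), and 55 lay between 30% and 70%. The share was 58.7% for HMGA1, 56.0% for her5, 58.7% for vox, 39.3% for vent, 46.7% for snai1b, 52.4% for gata6, 45.1% for noto, 41.6% for tbx16, 51.3% for foxh1 and 71.1% for klf2a, and ran from 23.5% for slc22a5 to 81.5% for LOC110524269, named after its value was seen. In the 3663 pairs already present at 1 dpf (at least 30 counts over the section A libraries) the median share was 25.7% (quartiles 15.4% and 37.3%). The S. fontinalis copy rose in 3205 of these, and the O. mykiss copy of these rose in 770, fell in 708 and was not called in 1727. Over all O. mykiss genes, factors from the O. mykiss genes alone turned 2656 higher and 5262 lower to 3889 and 2774. The pairs were not recounted with those factors, so the balance of 770 and 708 holds for the main factors only. By list, the pooled share in replicates 1 and 2 was 52.9% and 53.3% for 8 ribosomal protein pairs, 34.0% and 38.2% for 29 early zygotic pairs, 14.4% and 11.4% for 5 oocyte and egg pairs, and 7.66% and 9.46% for 6 germ plasm pairs. The highest was 96.8% and 95.8%, for 2 pairs of the follicle list (krt5 and the pair named fshr), and the other lists with pairs lay between.

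**Figure D4:**
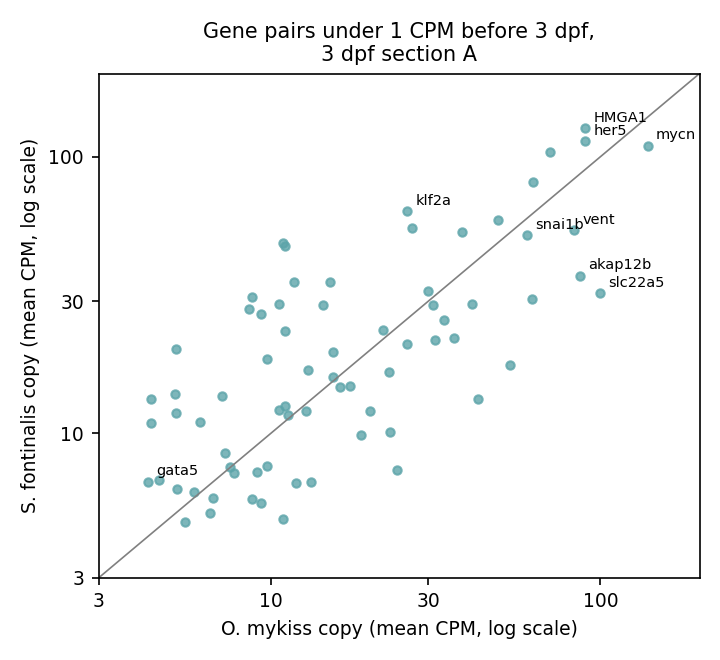
Mean CPM in section A at 3 dpf (n = 2) of the O. mykiss copy (horizontal, log scale) and the S. fontinalis copy (vertical, log scale) of the 73 one-to-one gene pairs under 1 CPM before 3 dpf. The line marks equal CPM; the median S. fontinalis share is 51.5%, and 55 pairs lie between 30% and 70%.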

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

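The test of the section difference across stages and the splits of the samples were planned, and the prediction on the parental share of newly expressed pairs was written before its result. The tests of misassigned reads, of RNA from outside the embryo and of egg groups, and the naming of O. mykiss increases, were chosen only after the result was seen.

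The difference between the animal and the vegetal section changed between 1 dpf and 3 dpf in 6616 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and in 4010 without 3 dpf section A replicate 1. Fitted changes are on the log2 scale, and where a group had 0 counts their size depends on the prior count and is no bound. The S. fontinalis genes with the largest change towards section A were prmt1 (18.52, adjusted p = 0.000198), psap (15.93, adjusted p = 0.000148, 140.3 ± 64.6 CPM in section A at 3 dpf and 0 counts in section B) and ago2 (15.87, adjusted p = 0.000321, 209 ± 92.5 CPM and 0 counts). phlpp2 changed by 15.47 (adjusted p = 0.0142, and 1 without 1 dpf section B replicate 1), and usp7, a deubiquitinase gene, by 14.66 (adjusted p = 0.00112, and 1 without 1 dpf section B replicate 2). The O. mykiss gene HMGA1 changed by 12.46 (adjusted p = 0.00159) and apoeb by 10.51 (adjusted p = 0.00231, and 0.084 without 1 dpf section B replicate 1). akap12b changed by 10.27 (adjusted p = 0.00981, and 1 without 1 dpf section B replicate 2), and itga4, an integrin gene, by 7.73 (adjusted p = 0.00911, and 0.162 without that library). fetub changed by 7.82 (adjusted p = 0.0283). Its adjusted p was 0.178 with DESeq2, 1 without 1 dpf section B replicate 3, 0.0663 without 3 dpf section A replicate 1 and 0.0522 without 3 dpf section B replicate 2.

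The O. mykiss genes with the largest change towards section B were kip1 (−3.25 ± 0.54, SE, adjusted p = 0.000676), at 2.68 ± 0.371 CPM in section A and 9.68 ± 2.09 in section B at 3 dpf (n = 2 each), and adgrl1a (−2.65 ± 0.53, adjusted p = 0.00234), at 3.64 ± 0.103 and 11.95 ± 1.95. otx2a, a head patterning homeobox gene, changed by −2.59 (adjusted p = 0.00961), but its adjusted p was 0.0553 in the compared libraries alone, 0.0614 without 3 dpf section A replicate 1 and 0.0513 without 3 dpf section B replicate 2. spen, a transcriptional repressor gene, changed by −2.48 ± 0.52 (adjusted p = 0.0034) and runx3 by −2.47 ± 0.24 (adjusted p = 1.26e-05). At 3 dpf spen measured 32.3 ± 1.80 CPM in section A and 37.6 ± 18.7 in section B (n = 2 each).

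The rise of S. fontinalis counts in section A at 3 dpf was weighed against misassigned reads and outside RNA. O. mykiss reads misassigned at a constant rate would leave the share per gene pair where it was. The lower of the 3 dpf section A medians was 25.8%, against 0.0261% to 0.530% in the other 18 libraries. This argues against misassignment at a constant rate, although the rise had already been seen in the library shares. With S. fontinalis RNA from outside and no transcription in the embryo, the O. mykiss copies of silent genes would stay at 0. Over 97 pairs without early RNA the median S. fontinalis share was 51.9%. A missing copy was set to 0 (13 O. mykiss and 11 S. fontinalis copies were missing). This median argues against outside RNA alone for these pairs as a set. It does not for single genes with a nearly all paternal share, such as the 13 pairs without an O. mykiss copy. Outside S. fontinalis RNA beside O. mykiss transcription in the embryo would also give a mixed share, so the test cannot exclude it. The prediction for transcription of both parental genomes, a median share between 30% and 70% among pairs with both copies present, was met at 51.5% over 73 pairs, but needing both copies removes one-sided pairs by construction, so the test that could have failed is the median over the 97 pairs, which lay in the same range. A candidate explanation is that both genomes were transcribed in the cells of the animal section by 3 dpf. The share of about 1.00% in the other libraries may hold reads that match both genomes, which was not tested. At 0 hpf, labelled as a non-fertilized or freshly fertilized egg, it was already 1.05% in section A and 0.997% in section B. That argues against transcription of the paternal genome as its source at 0 hpf.

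Calls between 0 hpf and 1 hpf in some models, 824 genes in section A from the compared libraries alone, were weighed against groups of eggs. By clustering of the O. mykiss genes of section B, the 10 eggs fell into 3 groups that cross the stages, of 4, 4 and 2 eggs, with correlations of at least 0.369 within groups and at most −0.109 between them, and both 0 hpf eggs fell into 1 group with 1 egg of 1 dpf and 1 of 3 dpf. Of the 704 O. mykiss genes called in section A, 98.2% differed with the same sign between the larger groups at 1 dpf (2 against 1 eggs) and 88.2% at 3 dpf (1 against 1 egg; all genes 68.5% and 60.1%), while the group of 2 eggs, which holds 2 of the 3 eggs of 1 hpf, had no later egg and was not tested. The groups come from counts of the same eggs, but were the same in 45 of 45 egg pairs when formed from the 14692 genes with an unadjusted p of at least 0.05 between these stages, although their correlations then overlapped (at least 0.108 within groups and at most 0.215 between them). A candidate explanation is that the eggs came from different mothers, which the labels do not record, and since no 1 hpf egg fell into the group of the 0 hpf eggs, stage and egg group are separated only through the later eggs, if the groups differ alike at each stage, in a model that called 0 genes in section A and 0 in section B (1438 and 2078 at an unadjusted p under 0.05).

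Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. For section A against B at 1 hpf and at 1 dpf, 1 split of 10, the real one, gave as many genes (5926 and 6947), and the highest other gave 0. Of the 4 splits that part all 3 pairs of sections 1 is the real one, and the others gave 0 too. Each other split sets libraries of both sections on each side, so the section difference itself widens the spread there. Few calls would follow in any case, and no conclusion is drawn from the 0. For 1 dpf against 1 hpf, 10 of 10 splits gave at least the real count of 0 in each section. The highest other was 0 in section A and 544 in section B, from the split that sets the 3 eggs of 1 egg group apart, a structure of the samples beyond stage. For the change of the section difference from 1 hpf to 1 dpf, 10 of 10 splits gave at least the real count of 0, and the highest other gave 0.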

How the results depend on the processing

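The factors from O. mykiss genes alone, the egg groups as a block and the list tests on O. mykiss genes alone were chosen after seeing the data; the other alternatives were planned. The counts of genes differing between the sections at 1 hpf, 1 dpf and 3 dpf, and between 1 dpf and 3 dpf in section A, kept within 1.5 times under all alternatives run except those named here. Of 580 results for named genes 0 reversed, and 92 lost their call under at least 1 alternative, 194 times by leaving out 1 library, 23 with the compared libraries alone, 18 with DESeq2, 14 with RLE factors, 14 with factors from O. mykiss genes, 5 with library sizes, 3 with the CPM minimum, and 1 each with the egg, the replicate number and the egg group as a block. The cause was not tested except where fewer genes or libraries entered. DESeq2 gave 2520 genes for section A against B at 0 hpf, 369 and 1423 for 1 hpf against 0 hpf in sections A and B, 99 and 105 for 1 dpf against 1 hpf, 78 for 3 dpf against 1 dpf in section B, and 1 for the change of the section difference from 0 hpf to 1 hpf. The compared libraries alone gave 3467 genes for the sections at 0 hpf, 824 and 666 for 1 hpf against 0 hpf in A and B, and 3 and 4232 for the change of the section difference from 0 hpf to 1 hpf and from 1 dpf to 3 dpf. The egg as a block gave 3037 at 0 hpf, and the list of translational control between the sections at 3 dpf then passed (adjusted p = 0.038 in place of 0.0603), as did chromatin regulators in the change from 0 hpf to 1 hpf (0.038 in place of 0.0562). The replicate number as a block gave 202 and 1611 genes for 1 hpf against 0 hpf and 1 and 4 for 1 dpf against 1 hpf in A and B. Egg groups as a block, found in the same counts so that lost calls follow in part by construction, gave 3325 and 9027 for the sections at 0 hpf and 1 hpf, 0 and 0 for 1 hpf against 0 hpf in A and B (1438 and 2078 at an unadjusted p under 0.05), 3 and 5 for 1 dpf against 1 hpf in A and B, and 4 for the change from 0 hpf to 1 hpf. An absolute log2 fold change of at least 1 left 3859 and 4546 between the sections at 1 hpf and 1 dpf. Library sizes alone gave 1, and a CPM minimum of 1 gave 3, for 1 dpf against 1 hpf in B, and the minimum, which tests fewer genes, gave 10338 for 3 dpf against 1 dpf in A and 4249 genes higher at 3 dpf than at each earlier stage. Allowing 1 count in the early libraries gave 1 gene detected after 1 hpf in B. Of 273 list tests 46 passed, 0 with an estimated correlation, and 2 with an estimated correlation on O. mykiss genes alone.

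Leaving out 1 library, with a lone sample assumed to vary like the other groups, gave 260 (without section A replicate 1) to 1419 genes between the sections at 0 hpf, 0 to 22 and 0 to 192 for 1 dpf against 1 hpf in A and B (the higher ones without 1 hpf replicate 1), 0 to 42 for 1 hpf against 0 hpf in B (without 1 hpf replicate 1), 0 to 2 for 3 dpf against 1 dpf in B (without 3 dpf replicate 1), and 4010 (without 3 dpf section A replicate 1) to 6397 for the change of the section difference from 1 dpf to 3 dpf. Genes detected after 1 hpf in B numbered 7 and 13 without 3 dpf section B replicate 1 and 2. With 2 libraries per group at 3 dpf and 3 at 1 dpf the simulated recovery of 4-fold changes of the section difference was 49%, so smaller shifts from 1 dpf to 3 dpf were often below detection.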

Other observations

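The values below belong to lists and genes outside the comparisons above, and no explanation was tested for them. Stress genes were unevenly placed in the early embryo. At 1 hpf hspa5 (LOC100135840), the chaperone of the endoplasmic reticulum, measured 78.2 ± 4.36 CPM in section A and 235 ± 39.8 in section B (n = 3 each, log2 fold change −1.59 ± 0.18, SE, edgeR adjusted p = 4.33e-06). dnajb9a and ddit4 were lower in section A by −2.87 ± 0.27 and −2.01 ± 0.19. Of 38 O. mykiss genes of the heat shock and stress list 16 were higher and 8 lower (16 and 12 adjusted over the list alone), and of 36 genes of apoptosis and its regulators 5 and 4 (5 and 4). From 1 dpf to 3 dpf in section A atf4a (LOC110508391) rose by 1.92 ± 0.31 and fosl2 fell by −1.24 ± 0.18 (adjusted p = 7.6e-05 and 3.08e-05). The stress list rose in 9 and fell in 9 of 38 (12 and 7 with factors from O. mykiss genes alone, 8 and 10 with library sizes), and the apoptosis list in 10 and 12 of 36 (11 and 9 with those factors, 9 and 15 with library sizes), so their directions depend on scaling.

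Signaling genes changed in part from 1 dpf to 3 dpf in section A. wls, the carrier of Wnt ligands, rose from 13.4 ± 4.23 (n = 3) to 47.7 ± 6.08 CPM (n = 2, 1.83 ± 0.30, edgeR adjusted p = 8.9e-05), and acvr2aa, an activin receptor gene, fell by −1.70 ± 0.29 (adjusted p = 0.000143). The Wnt list rose in 9 and fell in 9 of 41 O. mykiss genes (9 and 9 adjusted over the list alone), or 15 and 7 with factors from O. mykiss genes and 8 and 10 with library sizes. The Nodal and BMP list rose in 7 and fell in 5 of 30 (7 and 5), or 11 and 3, and 7 and 9. The mRNA decay list rose in 17 and fell in 16 of 73 (17 and 16), or 27 and 10, and 11 and 21. The polymerase II list rose in 9 and fell in 10 of 57 (7 and 9 adjusted over the list alone), or 20 and 5, and 5 and 14, with brd2a rising by 1.41 ± 0.17 and taf4a falling by −1.37 ± 0.19. Histone genes rose in 4 and fell in 0 of 9 (4 and 0 adjusted over the list alone; camera adjusted p = 0.0579).

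Markers of other cell types were few in the table. Of 12 O. mykiss sperm markers 2 rose and 4 fell in section A from 1 dpf to 3 dpf (2 and 4 adjusted over the list alone), with odf2a rising from 0.964 ± 1.10 to 24.5 ± 2.06 CPM (edgeR adjusted p = 0.000453). Of 7 follicle markers 1 rose, krt5 (0 counts at 1 dpf and 9.19 ± 3.02 CPM at 3 dpf, adjusted p = 0.00107, and 0.234 with DESeq2), and 0 fell. Of 2 blood markers tested 0 rose and 0 fell in edgeR's test (epb41a with adjusted p = 0.148). Of 4 liver and yolk markers fetub and apoc1 rose (apoc1 with adjusted p = 0.00176, and 0.251 with DESeq2) and tf fell (adjusted p = 0.0433, but 0.216 with RLE factors, 0.211 with DESeq2, 0.22 without 1 dpf section A replicate 1, and 0.0711 and 0.217 without 3 dpf section A replicates 1 and 2). The mitochondrially encoded list had 0 genes in the table. O. mykiss rRNA genes, 20 in number, took 0.0253% to 0.150% of the counts of a library.

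The size of the animal-vegetal difference varied between eggs. Set against the mean of the other eggs, the slope of the A over B log2 ratios was 0.454 in replicate 2 of 0 hpf and 0.924 in replicate 1, against 0.866 to 1.21 in the other 8 eggs, so 1 of the 2 eggs of 0 hpf had a weaker difference. Against 1269 calls at 0 hpf, leaving out the section A library of that egg gave 731 and leaving out its section B library 1419. Between 1 dpf and 3 dpf the A over B log2 fold changes of 15423 O. mykiss genes correlated at r = 0.681 across genes, below the r = 0.948 between 1 hpf and 1 dpf. Across the pairs present at 1 dpf, the S. fontinalis share at 3 dpf and the change of the O. mykiss copy correlated at rho = 0.448 across genes, which are not independent replicates.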
